A study of Bos taurus with 20 samples.

How the data were processed

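RNA from skin biopsies with epidermis, dermis and dermal connective tissue was measured on Agilent 2-colour arrays, per the labels. Biopsies were taken where horns form on the head of 4 polled (hornless), 4 scurred (with loose rudimentary horns) and 3 horned cattle, 11 animals in all, and, as control skin, elsewhere on the skull of 1 polled and 1 scurred animal. There were 1 male and 3 females among polled, 3 males and 1 female among scurred and 2 males and 1 female among horned animals. The polled and the scurred animal of a chip were of opposite sex on 4 of 4 chips, so horn type and sex overlap. There were 20 arrays on 5 chips. Each of chips 1 to 4 held 4 arrays that joined 1 polled, 1 scurred and 1 horned animal in a closed loop, with polled against horned measured with both dye orders. Chip 5 held horn site against control site for polled replicate 3 and scurred replicate 2, each with both dye orders. Horned replicate 2 was used on chips 2 and 4, and replicates are numbered by chip. These groups, and the join of files to animals, were read from the sample labels, and chip 1 was scanned on another day than the rest, per the file headers.

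The deposited scanner files give each spot's mean brightness as an intensity on a linear scale in both dyes, with the local background. They also give processed intensities, which per the file headers were background subtracted, detrended and dye normalized by the scanner software. The deposited log ratio of those files is a log10 value of red over green. Agilent Feature Extraction 9.5.1 is named in the submitters' processing notes. The deposited table of the series holds the same log10 ratios, which was checked against the scanner files and turned to log2 for use here. Of its columns, 14 had a slope of 1 against the log10 of red over green and 6, from exchanged dyes, a slope of −1, with column medians from −0.019 to 0.00929 on the log10 scale, so the values lie around 0. All differences given here are log2 ratios computed from the deposited intensities. The signal was well above background at 62.24% to 73.75% of spots, 2 spots at most were saturated, and the number of animals limits the precision.

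Mean intensities were corrected with normexp (offset 50) and normalized within arrays by loess in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the data.table package. Duplicate spots were averaged. Spots flagged in the deposited files as uneven or as outliers of their replicates were left out. Arrays with exchanged dyes correlated at r −0.946 to −0.821 on chips 1 to 4 and at −0.726 and −0.662 on chip 5, across probes, which are not independent replicates. Names were looked up for 21475 probes, with 9927 found by gene identifier, 3523 by accession, 2803 by the human gene named in the description, 297 by symbol and 86 by an older symbol. Placeholder names made of LOC and a number do not count as symbols, which left 16386 probes with a gene symbol. The rest kept the name in the file. The reference table served for these names only, and no genome was used. A probe was tested when well above background in at least 3 of the 11 animals (16309 probes), or in at least 2 of the 4 RNAs of chip 5 (16422 probes).

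The arrays of chips 1 to 4 were first reduced to 1 value per animal and probe, with a coefficient for dye. The 8 differences between each polled or scurred animal and the horned animal on its chip then entered 1 generalized least squares fit with terms for polled, scurred and male, so the chip acts as a block and sex is adjusted for. Moderated tests from limma (two-sided, 5 residual degrees of freedom) were adjusted by Benjamini and Hochberg over all probes of a comparison, with a threshold of 0.05. Values per animal or chip are not adjusted for sex. The block was checked once on channels taken separately. Deviations of polled and scurred animals from their group means correlated at 0.237, 0.286, 0.423 and −0.0828 on the same chip, against means of −0.132, −0.13, −0.0715 and 0.0575 for other chips, across 16309 probes, which are not independent replicates. Animals measured on 2 chips correlated with themselves at 0.998, 0.9978 and 0.9986, above any other animal on the second chip (0.976 at most). The site comparison tested the mean of 2 animals against 0, each animal being the mean of its 2 arrays.

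Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for named genes. They cover the layers and appendages of skin, cartilage and bone, WNT, hedgehog, BMP and FGF signalling, genes near the polled locus or named in earlier horn work, cell cycle, stress of handling, interferon response, mitochondria and ribosomes. Others hold markers of further cell types of a biopsy, namely skeletal muscle, fat, red cells, lymphocytes, macrophages, endothelium, melanocytes, nerve and smooth muscle. Of these, 29 with at least 5 measured genes were tested with camera on 1 probe per gene (11916 genes on chips 1 to 4), with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. The lists of Y-linked genes and of the X inactivation transcript were too short to test. Within 1 animal of chip 5, list medians were set against 10000 random lists of like signal. List medians are medians of log2 differences.

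Named genes are those past the threshold with 1 sign on every chip, up to 12 highest and 12 lowest. Where fewer than 10 passed, those next by p up to 10 that also have 1 sign on every chip are added. The rule adds the 4 members of lowest p of each list that passed or concerns horn-forming tissue, and of the polled locus list, the Y-linked genes, and for 1 animal of chip 5 the 10 highest and 10 lowest with both arrays on the same side, of which a part is printed. The 3 probes that differ between the sexes and 1 transcript described as Y-linked are its exceptions, chosen after their values were seen. Genes that the rule picks but that are withheld for evaluation are not reported here. A gene well above background in no RNA of 1 group is given as at least N-fold, computed against the background. Errors are standard errors of the fit unless called SD.

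Simulated data had the same design, with 100 probes changed by 1 and 100 by 2 on the log2 scale at once, in noise independent between probes. In polled against horned skin 47.6 and 89.3 of them were recovered, with 8.3 false calls on average over 10 draws. Of unchanged probes 4.97% had an unadjusted p under 0.05. With so many changes the adjusted threshold is easier to pass, so recovery would be lower where few probes change. In horn site against control site 0 of 100 changed by 2 were recovered. Alternatives were no background subtraction, Agilent's processed signals, median centring, scaling between arrays, no filter, a stricter filter, no sex term (for the sexes, no horn type term), no chip block, every array as a replicate, no dye term, trend and robust moderation, the deposited log10 ratios of the series on the log2 scale, horned replicate 2 as 2 animals, and each chip or animal left out. Without chip 2 the polled animals left are all female and the scurred animals all male. Horn type and sex are then told apart only through the horned animals. Control probes of the manufacturer were left out, as were per-animal levels of probes that mark sex.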

Results

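Skin of the horn-forming region differed between polled and horned cattle in 1 gene past the threshold. AIF1, a gene of macrophages and dendritic cells, fell by 1.71 on the log2 scale (SE 0.109, adjusted p 0.0174, limma), from −1.75 to −1.59 in the 4 polled animals, each against the horned animal on its chip. SFRP2, a secreted WNT modulator of fibroblasts, stood at −4.83 (SE 0.84) and FOXL2, a forkhead factor known from the polled intersex locus of goats, at −2.68 (SE 0.742). Both were lower in 4 of 4 polled animals, and neither passed (adjusted p 0.379 and 0.472). The epidermal genes COL17A1, a hemidesmosome collagen, and KRT5, the basal keratin, stood at 2.62 (SE 0.822, adjusted p 0.488) and 2.58 (SE 1.27, adjusted p 0.574), higher in 4 of 4. Of 16309 probes tested in 4 polled and 3 horned animals, 1495 (9.17%) had an unadjusted p under 0.05, 765 higher and 730 lower. With a chip or animal left out, AIF1 was called in 1 of 15 fits, that without scurred replicate 1, the animal least like the others, and it was not called under 5 other settings (adjusted p 0.0505 to 0.275).

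The genes next by p, among those with the same sign in 4 of 4 polled animals as the rule requires, did not pass (adjusted p from 0.222 to 0.315). IFI47, an interferon-inducible GTPase, was highest at 3.53 (SE 0.381), with 2.82 to 4.12 in single animals. PDZD2 stood at 1.21 (SE 0.16) and SIT1, an adaptor of T cells, at 1.01 (SE 0.143). On the lower side were SPON1, a matrix protein, at −1.89 (SE 0.25), LRAT, the enzyme that esterifies retinol, at −1.63 (SE 0.198), and LRRC25 at −1.04 (SE 0.131). SLITRK4 stood at −1.02 (SE 0.118), CADM3, an adhesion molecule of nerve, at −0.98 (SE 0.132), and PFKL, a phosphofructokinase, at −0.69 (SE 0.091).

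Epithelial gene lists lay higher in polled than in horned skin. The list of cornified envelope genes had a median of 1.28 with 26 of 27 genes higher (camera adjusted p 5.72e-05, adjusted p = 0.694 with an estimated correlation), and its chip medians ran from 0.21 to 1.63. SPINK5, a protease inhibitor of the upper epidermis, stood at 3.02 (SE 1.28), and ELOVL4, which makes very long chain fatty acids, at 3.25 (SE 1.47). With a chip or animal left out they went down to 1.47 and 1.19, and KRT5 to 0.89. Basal keratinocyte genes had a median of 0.575, 16 of 17 higher (adjusted p 0.00034, adjusted p = 0.603 with an estimated correlation), and lost the call without chip 2 (0.179) and without polled replicate 2 (0.237). Junction genes followed, with a median of 0.74 for desmosomes (15 of 18 higher, adjusted p 0.0103, adjusted p = 0.696 with an estimated correlation), CDH1 at 1.44 (SE 0.631) among them. The desmosome call was lost in 4 of 15 fits with a chip or animal left out, with a median down to 0.139 and CDH1 down to 0.61. Tight junction genes had a median of 0.80 with 16 of 17 higher (adjusted p 1.24e-08, adjusted p = 0.603 with an estimated correlation), and 4 of them were higher when adjusted over the list alone, against 0 over all probes. CLDN8, a claudin, stood at 2.14 (SE 0.583) and CGN, cingulin, at 2.05 (SE 0.504). The list of stress keratins and alarmins had a median of 1.23 but did not pass (adjusted p 0.16), and its member TGM2 lay the other way at −1.63 (SE 0.287), lower when adjusted over the list alone.

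Hair shaft, sebaceous and sweat gland genes lay higher too, while the follicle stem cell and papilla list did not pass. Hair shaft and inner root sheath genes had a median of 0.50, 18 of 19 higher (adjusted p 2.46e-07, adjusted p = 0.603 with an estimated correlation), and 10 were higher when adjusted over the list alone, against 0 over all probes. This height came mainly from some animals, since KRT27, an inner root sheath keratin, stood at 4.88 and 3.25 in polled replicates 2 and 4 and at 0.07 and 0.02 in replicates 1 and 3 (fitted 2.50, SE 0.622). PADI3, which modifies hair proteins, stood at 1.84 (SE 0.42) and KRT71 at 1.03 (SE 0.3). GATA3, a factor of the inner root sheath, was more even, from 1.9 to 3.1. Sebaceous and lipid synthesis genes had a median of 0.93, 17 of 24 higher (adjusted p 0.0267, adjusted p = 0.725 with an estimated correlation), with the desaturase SCD at 1.56 (SE 0.367). That call was lost with the stricter filter (median 0.318, adjusted p 0.143), with no sex term (0.773, adjusted p 0.0591) and in 4 of 15 fits with a chip or animal left out. Adjusted over the list alone, 1 was higher and 1 lower. Sweat gland genes had a median of 0.42, 19 of 21 higher (adjusted p 1.12e-06, adjusted p = 0.495 with an estimated correlation), with FOXA1 at 1.73 (SE 0.511), KRT7 at 1.25 (SE 0.371) and KRT18 at 1.11 (SE 0.304). Melanocyte markers moved with these lists, at a median of 1.01 with 12 of 13 higher (adjusted p 5.72e-05, adjusted p = 0.603 with an estimated correlation), PMEL standing at 1.74 (SE 0.767). Without chip 2 the melanocyte median was 0.248 and not called (adjusted p 0.154), and PMEL went down to 0.549 with a chip or animal left out.

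Genes of the collagen matrix lay lower, and those of vessels did so in the fit but not in every animal. The list of fibrillar collagens and matrix proteins had a median of −0.55, 41 of 47 lower (adjusted p 2.46e-07, adjusted p = 0.603 with an estimated correlation). FMOD, which binds collagen fibrils, stood at −2.30 (SE 0.668), COL5A2 at −1.16 (SE 0.317) and DPT at −1.05 (SE 0.275). Smooth muscle genes had a median of −0.41 (18 of 21 lower, adjusted p 0.000741, adjusted p = 0.603 with an estimated correlation) and endothelial genes of −0.30 (19 of 23 lower, adjusted p 0.0126, adjusted p = 0.729 with an estimated correlation). Both lists were higher in 2 of 4 polled animals, running from −0.955 to 0.361 and from −0.652 to 0.424. Schwann cell genes had a median of −0.21 (13 of 20 lower, adjusted p 0.0211, adjusted p = 0.603 with an estimated correlation), with the neurotrophin receptor NGFR at −1.04 (SE 0.271). The Schwann cell call was lost with no sex term (−0.122, adjusted p 0.084) and in 6 of 15 fits with a chip or animal left out, up to −0.0569, and the endothelial call with no sex term (−0.207, adjusted p 0.0763). Hedgehog pathway genes had a median of −0.17 (15 of 20 lower, adjusted p 0.0288, adjusted p = 0.603 with an estimated correlation), with SCUBE1 at −0.49 (SE 0.18). That call was lost under 5 other settings (adjusted p 0.0501 to 0.156) and in 5 of 15 fits with a chip or animal left out. Interferon response genes had a median of −0.36 (29 of 31 lower, adjusted p 5.72e-05, adjusted p = 0.603 with an estimated correlation), although IFI47 was higher. The interferon list was higher in 1 of 4 polled animals, running from −0.56 to 0.141.

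Marker lists of other cell types were called as well at the preset correlation. T and B lymphocyte markers had a median of 0.14, 18 of 24 higher (adjusted p 0.00195, adjusted p = 0.603 with an estimated correlation), and 4 were higher when adjusted over the list alone, against 0 over all probes. CD3E and CD3G, parts of the T cell receptor complex, stood at 0.72 (SE 0.124) and 0.79 (SE 0.153), ZAP70 at 1.45 (SE 0.365) and BLK at 1.32 (SE 0.311), each higher in 4 of 4. Red cell genes had a median of 0.88 (10 of 11 higher, adjusted p 0.0011, adjusted p = 0.603 with an estimated correlation), with HBB at 2.86 (SE 1.17) and HBA at 2.37 (SE 0.927). Skeletal muscle genes had a median of 1.0 (27 of 29 higher, adjusted p 0.00229, adjusted p = 0.729 with an estimated correlation), yet the chips ran from −0.83 to 2.95 and ACTA1, the muscle actin, from −0.85 to 6.76. Mitochondrial respiratory chain genes had a median of 0.19 (41 of 47 higher, adjusted p 0.00866, adjusted p = 0.819 with an estimated correlation). That call was lost with median centring (median 0.0121, adjusted p 0.221) and in 6 of 15 fits with a chip or animal left out, which ran from 0.0401 to 0.455.

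Other fixed lists did not pass in the fit chosen for polled against horned skin. Medians were −0.12 for macrophage and granulocyte genes (21 of 34 lower, adjusted p 0.0514), of which AIF1 is 1, 0.36 for immediate early and heat shock genes (adjusted p 0.0801), −0.03 for cell cycle genes (adjusted p 0.685), −0.0019 for ribosomal proteins (adjusted p 0.606) and −0.02 for cartilage and bone genes (adjusted p 0.848). The immediate early list passed under 4 other settings (adjusted p 0.0216 to 0.0435) and the macrophage list under 3 (adjusted p 0.0138 to 0.0478). Median centring also called stress keratins (adjusted p 0.0312) and ribosomal proteins (−0.293, adjusted p 6.63e-05). In the cartilage list RUNX2, a master factor of bone, stood at −1.33 (SE 0.511), from −1.83 to −1.13. The median was above 0 but the test pointed down for hair follicle stem cell and papilla genes (0.04, adjusted p 0.705), adipocyte genes (0.04, adjusted p 0.902), WNT genes (0.01, mean −0.16, adjusted p 0.806) and BMP and FGF genes (0.02, adjusted p 0.918). WNT genes held SFRP1 at −1.42 (SE 0.456) beside SFRP2, and the FGF genes held the ligands FGF18 at −1.23 (SE 0.283) and FGF10 at −1.03 (SE 0.325) against the receptor FGFR2 at 1.56 (SE 0.426) and the inhibitor SPRY2 at 1.01 (SE 0.252). Of 27 genes from the polled locus neighbourhood and earlier horn candidates, 12 were higher and 15 lower (median −0.02, adjusted p 0.649). The lowest p among them belonged to FOXL2, SLC5A3, a myo-inositol carrier at 0.81 (SE 0.233), IFNAR1 at −0.41 (SE 0.119) and IFNGR2 at −0.57 (SE 0.227), both interferon receptor chains.

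Of 29 lists, 18 passed with camera's preset correlation (20 without scurred replicate 1, 12 to 22 with any chip or animal left out) and 0 with an estimated correlation, and 5 of the 18 stayed called when any chip or animal was left out, those of tight junctions, hair shaft, sweat gland, red cells and interferon response. Without polled replicate 2, the 1 male among polled animals, the cornified median was 0.158 and the collagen median −0.0686, neither called, in a fit where sex and horn type overlap more. Of the others, skeletal muscle lost its call in 4 of 15 fits (down to 0.534), smooth muscle lost it in 3 and turned in 1, endothelium lost it in 2 and lymphocytes turned in 1. The 5 lists that stayed called moved too, their medians nearest 0 being 0.475 for tight junctions, 0.217 for hair shaft, 0.411 for sweat gland, 0.636 for red cells and −0.211 for interferon response. AIF1 stayed between −1.78 and −1.68 in all 15 such fits.

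**Figure D1:**
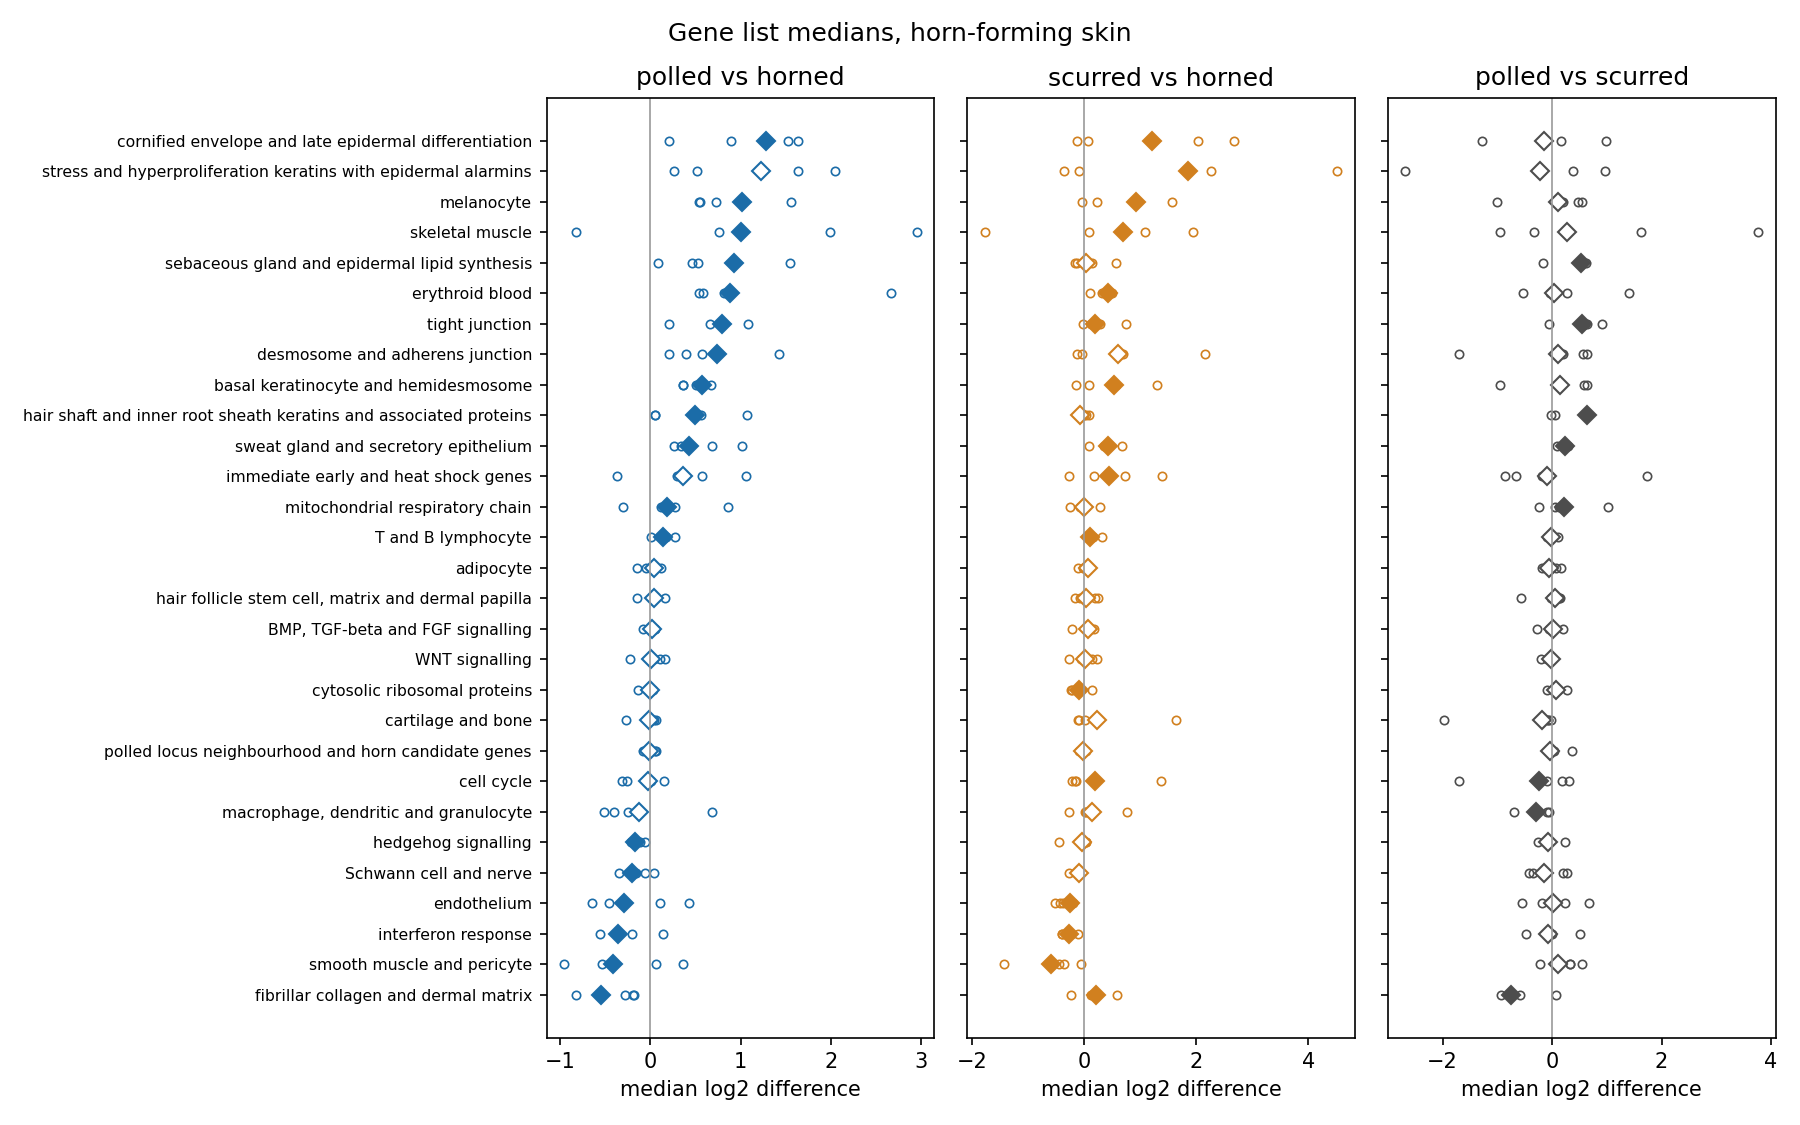
Median log2 difference of each fixed gene list in polled against horned, scurred against horned and polled against scurred skin. Diamonds are medians of the fitted values, filled where camera's adjusted p with the preset correlation was under 0.05, and circles are the 4 chips, which for the cornified list ran from 0.21 to 1.63 in polled against horned skin.

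Scurred skin, from animals with loose rudimentary horns, shared several of these features with polled skin when set against the same horned animals. IFI47 stood at 3.78 (SE 0.362, adjusted p 0.277), 3.51 to 4.68 in the 4 animals, and CADM3 at −1.09 (SE 0.126, adjusted p 0.443). MSX1, a homeobox factor of skull and appendage development, stood at −1.10 (SE 0.177), LRAT at −1.13 (SE 0.189) and CD3E at 0.81 (SE 0.118), each with the same sign in 4 of 4 scurred animals and an adjusted p of 1. None of 16309 probes passed in limma (4 scurred, 3 horned animals), also without scurred replicate 1, and 613 (3.76%) had an unadjusted p under 0.05, 255 higher and 358 lower. Also among the 10 of lowest p, with an adjusted p of 1, were PPIC at 1.13 (SE 0.207), SIT1 at 0.89 (SE 0.136), RASSF5 at 0.82 (SE 0.153), CD3G at 0.80 (SE 0.146) and PKIG, an inhibitor of protein kinase A, at −0.95 (SE 0.167). The rule takes these 10 only from genes with 1 sign on every chip, so their common sign is no evidence.

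Epidermal lists lay higher in scurred than in horned skin, chiefly through scurred replicates 1 and 2. Scurred replicate 1 stood apart, with a mean correlation of 0.927 with the other animals against 0.952 to 0.967 for the rest, across probes, which are not independent replicates. Cornified envelope genes had a median of 1.22 with 27 of 27 genes higher (adjusted p 2.33e-10, adjusted p = 0.573 with an estimated correlation), while chip medians ran from −0.13 to 2.68. LORICRIN, a main protein of the cornified envelope, stood at 5.33, 3.99, 0.39 and −0.52 in the 4 animals and CSTA at 6.55, 4.09, 0.91 and −0.37. Stress keratins and alarmins had a median of 1.85 (10 of 12 higher, adjusted p 0.011, adjusted p = 0.694 with an estimated correlation), with S100A8 and SERPINB4 at 7.63 and 7.98 in scurred replicate 1 and from −0.36 to 2.36 in the others. TGM2 lay lower in 4 of 4, at −1.42 (SE 0.273). Basal keratinocyte genes had a median of 0.53 (16 of 17 higher, adjusted p 0.00221, adjusted p = 0.694 with an estimated correlation), COL17A1 standing at 2.30 (SE 0.782) and KRT5 at 2.24 (SE 1.21). The stress and basal calls were each lost in 4 of 15 fits with a chip or animal left out, with medians down to 0.476 and 0.03. Tight junction genes had a median of 0.20 (13 of 17 higher, adjusted p 0.0189, adjusted p = 0.694 with an estimated correlation), with CGN at 1.13 (SE 0.48). That call was lost in 6 of 15 such fits, with a median down to 0.0673. Sweat gland genes had a median of 0.43 (18 of 21 higher, adjusted p 0.000265, adjusted p = 0.573 with an estimated correlation), with KRT19 at 0.93 (SE 0.347). Desmosome genes did not pass (median 0.61, adjusted p 0.0789), being higher on 2 chips and lower on 2, from −0.125 to 2.16, nor did hair shaft genes (median −0.07, adjusted p 0.382).

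Dermal lists split in scurred skin. Collagen and matrix genes lay higher at a median of 0.21, 35 of 47 higher (adjusted p 0.00265, adjusted p = 0.694 with an estimated correlation), with THBS2 at 1.20 (SE 0.351) and THBS1 at 0.57 (SE 0.231), both matrix thrombospondins. The call was lost in 5 of 15 fits with a chip or animal left out, which ran from 0.0534 to 0.393, and the list was lower on 1 of 4 chips (−0.226). TGFBI, a matrix protein induced by TGF-beta, stood at 0.99 (SE 0.272). Smooth muscle genes lay lower at −0.59, 19 of 21 lower (adjusted p 2.08e-07, adjusted p = 0.573 with an estimated correlation), MYH11 standing at −1.69 (SE 0.556). Without chip 1 the smooth muscle median was −0.187 and not called (adjusted p 0.0557), and over the fits with a chip or animal left out it rose to −0.0918. Endothelial genes lay at −0.24, 19 of 23 lower (adjusted p 0.000487, adjusted p = 0.694 with an estimated correlation), with VWF at −0.68 (SE 0.355) and KDR at −0.59 (SE 0.255). Interferon response genes had a median of −0.27, 28 of 31 lower (adjusted p 1.68e-05, adjusted p = 0.573 with an estimated correlation), with IFI35 at −0.52 (SE 0.138).

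Marker lists of melanocytes, lymphocytes, red cells and skeletal muscle also lay higher in scurred skin, unlike those of smooth muscle and endothelium. Melanocyte genes had a median of 0.93 (12 of 13 higher, adjusted p 0.000123, adjusted p = 0.573 with an estimated correlation), GPNMB standing at 1.44 (SE 0.5). T and B lymphocyte genes had a median of 0.11 (19 of 24 higher, adjusted p 1.6e-05, adjusted p = 0.573 with an estimated correlation), 3 of them higher when adjusted over the list alone, against 0 over all probes. Red cell genes had a median of 0.43 (10 of 11 higher, adjusted p 0.000214, adjusted p = 0.573 with an estimated correlation), with HBB at 3.51 (SE 1.11). Skeletal muscle genes had a median of 0.69 (25 of 29 higher, adjusted p 0.00652, adjusted p = 0.78 with an estimated correlation), yet the chips ran from −1.77 to 1.95 and the call was lost with no sex term (adjusted p 0.171). Immediate early and heat shock genes had a median of 0.45 (29 of 34 higher, adjusted p 0.00311, adjusted p = 0.694 with an estimated correlation), with FOSL1 at 0.85 (SE 0.276), and ribosomal protein genes of −0.09 (60 of 79 lower, adjusted p 0.00288, adjusted p = 0.694 with an estimated correlation). Cell cycle genes had a median of 0.195 (41 of 50 higher, adjusted p 0.0498, adjusted p = 0.837 with an estimated correlation). It was −0.242 without scurred replicate 1, and of 15 fits with a chip or animal left out the call was lost in 4 and turned in 3. That call was also lost under 6 other settings, with adjusted p from 0.0577 to 0.521 and a median of 0.0604 with scaling. The ribosomal call was lost with Agilent's signals (adjusted p 0.148) and the series matrix (0.147), and the tight junction call with the stricter filter (0.0513).

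In scurred against horned skin 16 of 29 lists passed with the preset correlation (15 without scurred replicate 1, 13 to 17 with any chip or animal left out) and 0 with an estimated correlation, and 6 of the 16 stayed called when any chip or animal was left out, those of cornified envelope, sweat gland, red cells, lymphocytes, melanocytes and interferon response. Their medians nearest 0 were 0.602 for cornified genes, 0.198 for sweat gland, 0.206 for red cells, 0.0955 for lymphocytes, 0.208 for melanocytes and −0.104 for interferon response. Of 15 such fits ribosomal proteins lost their call in 7, skeletal muscle in 4 (down to 0.175) and endothelium in 3, while immediate early genes lost it in 3 and turned in 2. Both comparisons use the same 3 horned animals. Horned replicate 2 serves chips 2 and 4 and the others serve the rest, but a split by horned animal was not run. Across 16309 probes, which are not independent replicates, log2 values of the 2 comparisons correlated at r 0.694 against 0.508 in simulations with no effect (covariance 0.104 against 0.0518). Part of this can come from the shared animals. The simulated values are given without their spread over 100 draws. The excess over them therefore does not show features common to polled and scurred skin.

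**Figure D2:**
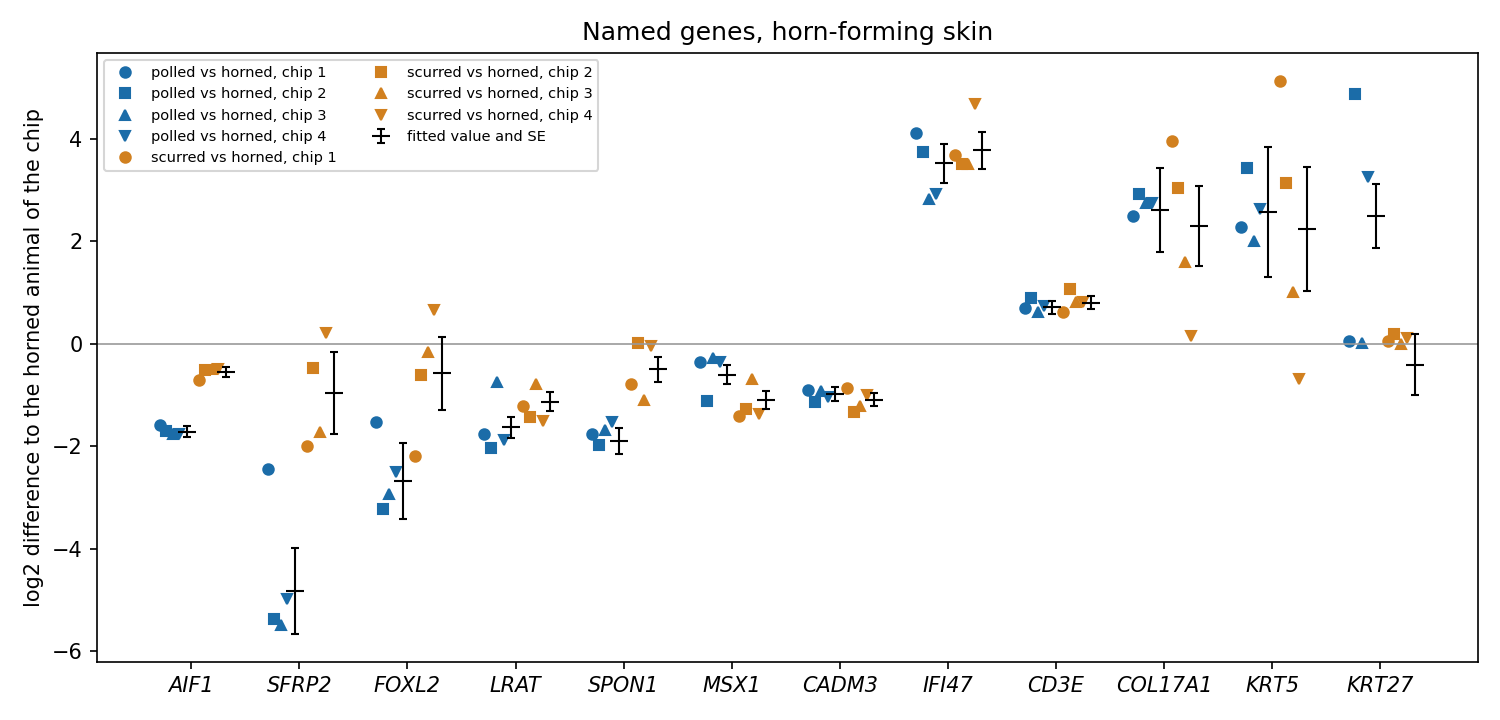
Log2 difference of 12 named genes between each polled (blue) or scurred (orange) animal and the horned animal of its chip, 1 marker shape per chip, with the fitted value and its SE in black. AIF1 lay between −1.75 and −1.59 in polled animals, and KRT27 at 4.88 and 3.25 in polled replicates 2 and 4.

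Set directly against scurred skin, polled skin had lower medians for lists of macrophage and collagen matrix genes and higher medians for hair shaft and tight junction genes. These 4 were called at the preset correlation only (adjusted p = 0.767 to 0.886 with an estimated correlation). AIF1 stood at −1.16 (SE 0.105, adjusted p 0.192), lower in 4 of 4 chips, CD14, the endotoxin co-receptor of monocytes, at −0.95 (SE 0.173) and TYROBP at −0.72 (SE 0.241). SFRP2 stood at −3.88 (SE 0.815) and was lower in 4 of 4, from −5.20 to −0.46. FOXL2 stood at −2.10 (SE 0.72), lower in 3 of 4 chips and higher at 0.68 on chip 1. No probe of 16309 passed in limma (4 polled, 4 scurred animals), also without scurred replicate 1, and 991 (6.08%) had an unadjusted p under 0.05, 513 higher and 478 lower.

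Other genes of lowest p, among those with 1 sign in 4 of 4 chips as the rule requires, had an adjusted p of 0.664 to 0.784. PON3, a paraoxonase, stood at 2.15 (SE 0.375) and NEFH, a neurofilament, at 1.31 (SE 0.213). PPIC stood at −1.40 (SE 0.211), SPON1 at −1.39 (SE 0.242), the chemokine CCL4 at −1.18 (SE 0.206), CD109 at −1.05 (SE 0.127), LRRC25 at −0.94 (SE 0.127), PFKP at −0.83 (SE 0.137) and PFKL at −0.53 (SE 0.0883).

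The list of collagens and matrix proteins had a median of −0.74 with 43 of 47 lower (adjusted p 4.24e-17, adjusted p = 0.767 with an estimated correlation), and 20 had an unadjusted p under 0.05. COL5A2 stood at −1.43 (SE 0.308), COL5A1 at −1.34 (SE 0.311) and COL6A1 at −0.62 (SE 0.157), and TGFBI at −1.33 (SE 0.277). Macrophage and granulocyte genes moved with it, at a median of −0.29 with 26 of 34 lower (adjusted p 9.14e-05, adjusted p = 0.886 with an estimated correlation), 2 of them when adjusted over the list alone, against 0 over all probes. Hair shaft genes had a median of 0.63 with 18 of 19 higher (adjusted p 6.02e-11, adjusted p = 0.767 with an estimated correlation), 9 of them when adjusted over the list alone, against 0 over all probes. KRT27 stood at 4.69 and 3.13 on chips 2 and 4 and at 0.0049 and 0.03 on the others, and PADI3 at 1.89 (SE 0.407). KRTAP1-1, a hair matrix protein not above background in scurred skin, was at least 1.93-fold higher in the group mean, a bound set by the background, with 2.19 and 1.38 on chips 2 and 4 and −0.0043 and 0.03 on chips 1 and 3. Tight junction genes had a median of 0.54 with 16 of 17 higher (adjusted p 1.1e-06, adjusted p = 0.767 with an estimated correlation), including CLDN8 at 1.95 (SE 0.566), CLDN7 at 0.82 (SE 0.27) and F11R at 0.69 (SE 0.206). Sebaceous genes had a median of 0.52 (17 of 24 higher, adjusted p 0.0242, adjusted p = 0.886 with an estimated correlation), SCD standing at 1.20 (SE 0.356). Sweat gland genes had a median of 0.23 (15 of 21 higher, adjusted p 0.0197, adjusted p = 0.817 with an estimated correlation), KRT18 standing at 1.02 (SE 0.295). The sebaceous call was lost with the stricter filter (adjusted p 0.0592), no sex term (0.0747) and no replicate block for the chip (0.0985), and the sweat gland call with scaling (0.133, adjusted p 0.0962).

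Mitochondrial genes had a median of 0.21 in polled against scurred skin (44 of 47 higher, adjusted p 0.00116, adjusted p = 0.886 with an estimated correlation) and cell cycle genes of −0.24 (42 of 50 lower, adjusted p 0.0286, adjusted p = 0.886 with an estimated correlation). Without scurred replicate 1 the cell cycle median turned to 0.11, and 3 other settings lost the call (adjusted p 0.0514 to 0.21). Of 15 fits with a chip or animal left out, 4 lost the cell cycle call and 2 turned it. Cornified genes (−0.15, 11 of 27 higher, adjusted p 0.456) and basal keratinocyte genes (0.15, 13 of 17 higher, adjusted p 0.291) did not pass. The median was above 0 but the test pointed down for hair follicle stem cell genes (0.05, mean −0.01) and for BMP and FGF genes (0.02, mean −0.0024). In the latter GREM1, a BMP antagonist, stood at 0.79 (SE 0.213). MSX1 was higher in polled than in scurred skin in 4 of 4 chips, at 0.50 (SE 0.181), and IFNAR1 stood at −0.29 (SE 0.116). Of 29 lists, 8 passed with the preset correlation, 16 without scurred replicate 1 and 0 with an estimated correlation. Hair shaft and macrophage genes were the 2 lists called whichever chip or animal was left out, with medians from 0.242 to 1.1 and from −0.567 to −0.162. The collagen list lost its call without chip 2 (median −0.0228), as did tight junction genes without polled replicate 2 (0.225). Sebaceous and sweat gland genes each lost the call in 3 of 15 fits and turned in 1, and mitochondrial genes lost it in 2 and turned in 1.

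Males and females differed in 3 probes, all lower in males. The probes carry only transcript identifiers of expressed sequence tags, described in the file as lying on chromosome 24 near each other, and are named although they fall outside the rule for named genes, being chosen after their values were seen. BI535042 fell by 6.48 (SE 0.134, adjusted p 7.84e-06), AW313543 fell by 5.17 (SE 0.36, adjusted p 0.011) and BE808926 fell by 4.45 (SE 0.172, adjusted p 0.000294), in limma with 6 males and 5 females. All 3 were higher in the female of each of 10 pairs of opposite sex joined by arrays, some of them across chips 2 and 4 through horned replicate 2. This does not test the labels, since the probes were chosen by them. Of Y-linked genes, TSPY stood at 1.46 (SE 0.347, adjusted p 1) and ZFY at −0.12 (SE 0.0854, adjusted p 1). The ZFY probe was well above background in 11 of 11 animals, females included, so its value does not tell the sexes apart. CB440118, described in the file as similar to the Y-linked UTY, stood at 1.33 (SE 0.135, adjusted p 0.102) and passed under some other settings, among them Agilent's processed signals and no horn type term. The probes of TSPY and CB440118 were each well above background in 6 animals. In all, 353 of 16309 probes (2.16%) had an unadjusted p under 0.05, 153 higher and 200 lower.

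Skeletal muscle genes set the sexes apart most among the lists, with a median of −1.49 and 29 of 29 lower in males (adjusted p 1.6e-19, adjusted p = 0.772 with an estimated correlation). Hair shaft genes had a median of 0.32 (16 of 19 higher, adjusted p 2.09e-09) and cartilage and bone genes of 0.35 (21 of 23 higher, adjusted p 0.00601), both with adjusted p = 0.772 with an estimated correlation. Lower medians belonged to collagen and matrix genes at −0.19 (38 of 47 lower, adjusted p 0.00089), smooth muscle at −0.18 (18 of 21, adjusted p 0.00409), endothelium at −0.12 (19 of 23, adjusted p 0.00409), Schwann cells at −0.11 (14 of 20, adjusted p 0.0222) and the polled locus neighbourhood at −0.07 (21 of 27, adjusted p 0.0328). Each of these 5 had adjusted p = 0.772 with an estimated correlation. The hair shaft call was lost with no horn type term (0.138, adjusted p 0.236) and the stricter filter (0.214, adjusted p 0.105), and ran from 0.055 to 0.56 with a chip or animal left out. No replicate block for the chip lost the cartilage call (0.22, adjusted p 0.133), and no horn type term those of Schwann cells (adjusted p 0.187) and the polled locus (0.0935). BMP and FGF genes had a median of −8.31e-05 while their mean and test pointed up. The 8 lists passed with the preset correlation (8 without scurred replicate 1), and muscle was the 1 list called whichever chip or animal was left out, since collagen genes turned to a median of 0.28 and smooth muscle genes to 0.0071 without polled replicate 2. Cartilage and endothelium each lost the call in 4 of 15 fits, cartilage running from 0.0328 to 0.93, Schwann cells lost it in 5 and turned in 1, and the polled locus lost it in 6 and turned in 2.

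Horn site skin was compared with control skin of the skull in 1 polled and 1 scurred animal, and both had more signal for nerve sheath and macrophage genes and less for dividing cells at the horn site. PMP2, a protein of peripheral myelin, stood at 3.16 (SE 0.215), and the complement genes C1QB and C1QA at 1.80 (SE 0.28) and 1.36 (SE 0.103). Cell cycle genes lay at −0.47 and −0.49 in the 2 animals. With 2 animals and 1 residual degree of freedom, none of 16422 probes passed in limma (lowest adjusted p 0.934), and 805 (4.9%) had an unadjusted p under 0.05, 452 higher and 353 lower. The list test with an estimated correlation rests on the same 1 degree of freedom here. It could hardly pass any list, so its values below decide nothing.

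Cell cycle genes had a fitted median of −0.49 with 48 of 50 lower (adjusted p 2.39e-25, adjusted p = 0.777 with an estimated correlation), 26 of them lower when adjusted over the list alone, against 0 over all probes. RRM2, a subunit of ribonucleotide reductase, stood at −1.09 (SE 0.132), CCNB1 at −0.81 (SE 0.104) and CDK1 at −0.79 (SE 0.105). Immediate early genes lay lower too, at a median of −0.35 with 30 of 34 lower (adjusted p 3.87e-08, adjusted p = 0.777 with an estimated correlation), CCN2 standing at −1.08 (SE 0.102) and FOSB at −1.05 (SE 0.143). This came mainly from the polled animal, at −0.707 against −0.11 in the scurred one. Mitochondrial genes had a median of −0.14 (41 of 47 lower, adjusted p 8.68e-05, adjusted p = 0.777 with an estimated correlation). Smooth muscle genes had a median of −0.16 (15 of 21 lower, adjusted p 0.00612, adjusted p = 0.777 with an estimated correlation), 1 of them lower when adjusted over the list alone, with the actin ACTG2 at −1.35 (SE 0.104) and CNN1, calponin, at −1.07 (SE 0.166). Here too the polled animal lay lower, at −0.393 against −0.0811 in the scurred one. Melanocyte genes had a median of −0.19 (9 of 13 lower, adjusted p 0.0264, adjusted p = 0.777 with an estimated correlation), 2 of them lower when adjusted over the list alone, with MLANA at −1.02 (SE 0.217), PMEL at −0.98 (SE 0.133) and TYR at −0.75 (SE 0.108). The melanocyte median was −0.345 in the scurred and −0.0076 in the polled animal, and the call was lost with median centring (adjusted p 0.0894) and with the stricter filter (0.0865).

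Macrophage genes had a median of 0.46 at the horn site with 29 of 34 higher (adjusted p 1.48e-12, adjusted p = 0.777 with an estimated correlation), 1 of them when adjusted over the list alone. Schwann cell genes had a median of 0.20 with 14 of 18 higher (adjusted p 2.65e-05, adjusted p = 0.777 with an estimated correlation), 5 of them when adjusted over the list alone, among which CDH19 stood at 0.78 (SE 0.112) and S100B at 0.71 (SE 0.107). Skeletal muscle genes had a median of 1.45 with 27 of 27 higher (adjusted p 2.15e-12, adjusted p = 0.777 with an estimated correlation), 1 when adjusted over the list alone, but stood at 2.85 in the scurred and 0.18 in the polled animal. MYH1, a myosin of fast muscle, was the exception at 3.33 (SE 0.296), with 2.85 in the polled animal. Adipocyte genes had a median of 0.13 (13 of 19 higher, adjusted p 0.0201, adjusted p = 0.777 with an estimated correlation), with LPL at 1.20 (SE 0.213) and CFD at 0.80 (SE 0.102). Endothelial genes had a median of 0.36 (20 of 23 higher, adjusted p 0.000447, adjusted p = 0.777 with an estimated correlation), from −0.02 to 0.78 in the 2 animals, SELE lying the other way at −0.997 (SE 0.178). Median centring lost the endothelial call (0.0356, adjusted p 0.107) and Agilent's signals those of adipocyte (adjusted p 0.0536) and ribosomal genes (0.161). Ribosomal protein genes had a median of 0.07 (59 of 79 higher, adjusted p 0.00286, adjusted p = 0.777 with an estimated correlation), which median centring turned to −0.32. It was 0.14 in the polled and 0.0115 in the scurred animal.

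Collagen and matrix genes had a fitted median of 0.18 (33 of 47 higher, adjusted p 0.00286, adjusted p = 0.777 with an estimated correlation), but the 2 animals lay apart, at 0.39 in the scurred (39 of 47 higher) and −0.104 in the polled one (16 of 47 higher). Median centring turned the fitted value to −0.111. The list held POSTN, periostin, at 1.71 (SE 0.443) and ASPN, asporin, at 0.78 (SE 0.17). Of the WNT and BMP genes, whose lists did not pass, SFRP5 stood at 1.23 (SE 0.111) and GREM1 at −1.02 (SE 0.127). FOXL2, not above background in control skin, was at least 3.16-fold higher at the horn site, and ZEB2, a factor named in earlier work on polled cattle, stood at 0.50 (SE 0.125). Genes of lowest p, among those with 1 sign in both animals as the rule requires, included PLLP, a myelin protein, at 1.73 (SE 0.142) and AGT, angiotensinogen, at 1.51 (SE 0.109). Others were RNASE6 at 1.40 (SE 0.13), BRB at 1.18 (SE 0.103) and PEX5L at 1.11 (SE 0.102). Hair shaft genes had a median of −0.50 (13 of 15 lower, adjusted p 0.0264, adjusted p = 0.803 with an estimated correlation) that came from the scurred animal. That call was lost under 4 other settings, with adjusted p from 0.0536 to 0.27, the median being −0.128 with the stricter filter. The median was below 0 but the test pointed up for cartilage and bone genes (−0.02, mean 0.02) and WNT genes (−0.03, mean 0.13), and sweat gland genes had a median of −0.05 and a mean of 0.0074. Of 29 lists, 13 passed with the preset correlation and 0 with an estimated correlation, a test that with 1 residual degree of freedom could hardly pass any.

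The 2 animals differed in epidermal genes, and across 16422 probes, which are not independent replicates, their ratios correlated at r −0.0764. In the polled animal the highest and lowest genes included CD5L, a macrophage protein, at 3.05, LCN9 at 3.36, GSTA2 at 2.90 and KRT19 at 2.25, against KRT10, a keratin of the upper epidermis, at −4.44, SCG2 at −4.00, IL6 at −4.00, S100A7 at −3.07, CCL2 at −2.83 and S100A8 at −2.67. In the scurred animal KRT10 stood at 3.92. Muscle genes were highest there, with MYL1 at 6.25, ANKRD1 at 6.02, ACTA1 at 5.71 and MYH7 at 5.65, MYOT at least 39.6-fold higher, and SFRP2 at 5.05. Hair genes were lowest, with KRT25 at −6.16, KRT27 at −4.66, TCHH at −3.35 and PADI3 at −3.15, beside the chemokine CXCL13 at −2.65. These are values from 2 arrays of the same RNAs with exchanged dyes and were not tested.

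**Figure D3:**
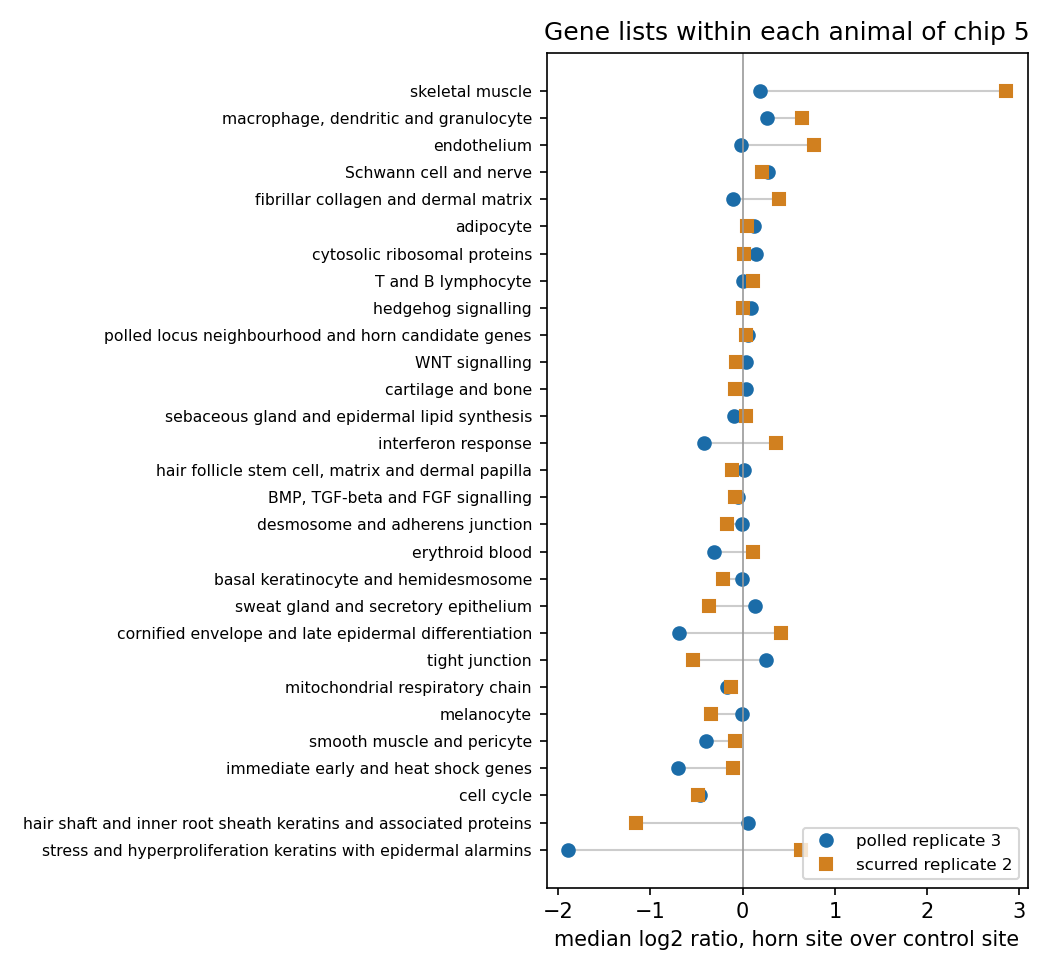
Median log2 ratio of horn site over control site for each fixed gene list in polled replicate 3 (circles) and scurred replicate 2 (squares), each the mean of 2 arrays with exchanged dyes. Cell cycle genes lay at −0.47 and −0.49, and skeletal muscle genes at 0.18 and 2.85.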

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

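The tests of explanations in this part were all chosen only after the result was seen. Of 167 groups of 4 values examined, 14 held a value that stood apart from the others, where chance gives about 1 in 20. Mean correlation with the other animals was 0.927 in scurred replicate 1, against 0.964 in the next scurred animal. In polled against horned skin, polled replicate 2 stood apart in collagen and matrix genes (median −0.82, next −0.277), MSX1 (−1.11) and PFKL (−0.80). In the same comparison, polled replicate 1 stood apart in red cell genes (2.67, next 0.815) and SFRP2 (−2.45), and polled replicate 4 in ZAP70 (0.52). Against horned skin, scurred replicate 1 stood apart in cell cycle genes (1.38, next −0.139) and scurred replicate 4 in IFI47 (4.68). In polled against scurred skin, chip 1 stood apart in sebaceous genes (−0.164), AIF1 (−0.88) and FOXL2 (0.68, next −2.63), chip 2 in NEFH (1.93) and chip 3 in PON3 (3.22).

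At the horn site against control skin, 6 lists lay at opposite ends of the random lists in the 2 animals of chip 5, a difference that was not tested. Scurred replicate 2 minus polled replicate 3, the medians differed by 2.52 for stress keratins and alarmins, 1.11 for cornified genes, 0.78 for interferon response genes, 0.49 for collagen and matrix genes, −0.49 for sweat gland genes and −0.79 for tight junction genes.

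Epidermal lists were higher in polled and in scurred than in horned skin. Background correction or normalization is argued against, because the cornified list stayed called with a median of at least 0.993 in both comparisons under 5 alternatives each. Those calls rest on the preset correlation (adjusted p = 0.694 and 0.573 with an estimated correlation). A smaller share of dermis in the polled biopsies cannot be told apart, since all 4 dermal lists had fitted medians below 0 but endothelium, at −0.296, lay within its SD of 0.498 over the chips, and it and smooth muscle were higher in 2 of 4 polled animals. For the scurred biopsies it cannot be told apart either, because the collagen median there was 0.213 with an SD of 0.335 over the chips while the other medians were below 0. Horn type itself stays open as untested. Of the 35 splits of the animals, most of which put animals of 1 chip in the same group, 6 and 13 gave a cornified median as large as the real 1.28 and 1.22 (highest other −1.90 and −2.15), so they do not exclude chance, and the 4 that part every pair of a chip are too few for a share under 0.05 (highest other 1.29 and 1.41).

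Skeletal muscle genes were lower in male than in female skin. Muscle carried into single biopsies cannot be told apart from sex, since the genes of the list moved together within the sexes, with a mean correlation between genes of 0.628, but cornified genes did so more (0.681). Muscle signal also differed with sex held constant. Females ran from −1.33 to 3.68. Horn site over control site was 2.85 in scurred replicate 2 (27 of 27 genes higher) and 0.182 in polled replicate 3, both female. Sex cannot give these differences, but they leave the one between the sexes undecided. In 4 of 5 females the list lay above every male, so sex itself stays open as untested. Chance is not excluded either, since 14 of the 100 splits drawn gave a median as large as −1.49, the highest other being 2.65.

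Collagen and matrix genes were lower in polled than in scurred skin. Polled replicate 2 alone cannot be told apart. Without that animal the median was −0.206, still called at the preset correlation but within the SD of 0.446 over the chips. That SD includes the chip of polled replicate 2 and is a spread of single chips, not an error of the fitted median. It therefore cannot decide how much rests on that animal. Without the whole of chip 2 it was −0.0228 and not called, but the polled animals left are then all female and the scurred animals all male. A larger share of epidermis in the polled biopsies cannot be told apart from horn type, since the cornified median was −0.151 with an SD of 0.935 over the chips. Horn type stays open as untested, and 4 of the 35 splits gave a median as large as −0.74 (highest other −0.90), so they do not exclude chance. The 8 splits that part every pair of a chip are too few for a share under 0.05 (highest other 0.65).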

How the results depend on the processing

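All settings in this part were planned before the data were examined. Each cause below was not tested unless named. In simulated data of this design, with many probes changed at once, 47.6 of 100 changed by 1 were recovered. Changes of that size can be missed, more so where few probes change, and signal over background limits folds of dim genes. Of named gene values under settings other than leaving out a chip or animal, 1713 of 1827 kept direction and side of the threshold. Of the rest 5 lost the call, all of them AIF1 in polled against horned skin, 109 gained one, most of them with every array as a replicate, and 0 turned. Of 910 list values 779 kept both, 105 lost the call, most of them with an estimated correlation, 9 gained it and 17 turned, by the sign of the median or of the test. With chips or animals left out, 1830 of 1845 gene values and 718 of 915 list values kept both. All of these genes but AIF1 in polled against horned skin were uncalled in the chosen fit, so most gene values had no call to lose. AIF1 lost its call in 14 of the fits.

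In polled against horned skin the count fell from 1 to 0 with Agilent's processed signals (1592 at unadjusted p under 0.05, limma), median centring (1146), scaling (1462) and the series matrix (1585). Every array as a replicate gave 4372, since arrays of the same RNA then count as animals. The same setting gave 391 in scurred against horned, 1178 in polled against scurred and 669 between the sexes. AIF1 itself stood between −1.86 and −1.64 over these settings, with adjusted p from 8.19e-10 to 0.275. With no replicate block it was −1.76 (adjusted p 0.275) while 1 other probe, IGSF1, passed. Median centring called 1 probe in scurred against horned skin, IFI47 (adjusted p 0.0196, range 8.37e-06 to 0.484), and no sex term called 1 in polled against scurred, AIF1 (adjusted p 0.0176, range 2.83e-06 to 1). Between the sexes the count was 6 with Agilent's processed signals, 6 with no horn type term, 5 with no replicate block, 5 with the series matrix and 1 with the stricter filter, which tests fewer probes. With no replicate block scurred against horned and polled against scurred skin gave 0 and 0, with 443 and 403 at an unadjusted p under 0.05. The site comparison gave 0 under every setting tried.

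An estimated correlation left 0 lists in each of the 5 comparisons (0, 0, 0, 0 and 0), and median centring gave 13 lists between the sexes. In the site comparison, with 1 residual degree of freedom, a list could hardly pass with an estimated correlation. Median centring moved the median of all probes by −0.112 in the site comparison, where ribosomal proteins turned to −0.32 and the median of collagen genes to −0.111 while their test still pointed up. In polled against horned skin it also turned the test for follicle stem cell (median 0.03), cartilage (0.00388), adipocyte (0.0295) and BMP and FGF genes (−0.074). Other turns in that comparison also concerned lists that had not passed. Adipocyte genes stood at 0.0255 with no filter, 0.183 with the stricter filter, 0.026 with no sex term and 0.0414 with the shared horned animal as 2 animals. BMP and FGF genes stood at −0.0459 with Agilent's signals and with the series matrix, 0.016 with the stricter filter, 0.00234 with no replicate block and 0.00618 with the shared animal as 2, where WNT genes stood at 0.022. Collagen genes between the sexes turned to 0.0856 with no horn type term.

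With 1 chip or animal left out, probes called ranged from 0 to 1 in polled against horned, 0 to 1 in scurred against horned (1 without polled replicate 1) and 1 to 4 between the sexes (1 without chip 2). Lists called ranged from 12 to 22 in polled against horned, 13 to 17 in scurred against horned, 7 to 16 in polled against scurred (16 without scurred replicate 1) and 6 to 17 between the sexes (17 without chip 2). In polled against horned skin the list medians that turned ran from −0.181 (without polled replicate 2) to 1.72 for stress keratins, −0.127 to 0.0992 for follicle stem cells, and −0.00242 (without polled replicate 2) to 1.15 for sebaceous genes. They ran from −0.281 to 0.793 for cartilage, −0.0427 to 0.128 for fat, −0.027 (without chip 2) to 0.325 for lymphocytes, −0.423 to 0.00961 for macrophages and −0.623 to 0.0235 (without chip 2) for smooth muscle. The polled locus list ran from −0.0491 to 0.0629, WNT genes from −0.188 to 0.0655 and BMP and FGF genes from −0.137 to 0.123. The range was −0.474 to 0.337 for cell cycle, −0.31 to 0.774 for immediate early and −0.135 to 0.0804 for ribosomal genes. In scurred against horned skin they ran from −0.242 (without scurred replicate 1) to 0.486 for cell cycle and −0.0511 (without horned replicate 2) to 0.86 for immediate early genes. In polled against scurred skin they ran from −0.128 to 1.11 for sebaceous and −0.0184 to 0.448 for sweat gland genes (both lowest without polled replicate 2), −0.944 to 0.121 (without chip 1) for cell cycle and −0.0275 (without chip 4) to 0.549 for mitochondrial genes. Between the sexes they ran from −0.405 to 0.464 for collagen, −0.351 to 0.37 for smooth muscle and −0.105 to 0.0395 for the polled locus, each highest without chip 2. There the Schwann cell test turned while its median stayed below 0, from −0.153 to −0.0161. Either animal of chip 5 alone gives no test, and every array as a replicate no list test.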

Other observations

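Skeletal muscle genes varied widely between animals. Relative to the mean of all animals, the median of 29 muscle genes was 3.68 in polled replicate 4, 1.39 in polled replicate 1, 1.11 in horned replicate 2 and 0.971 in scurred replicate 2, all females. It was −1.33 in polled replicate 3, the remaining female, and the males ran from −2.30 to 0.07. Cornified genes were highest in scurred replicate 1 at 2.32 and scurred replicate 2 at 1.18, and lowest in scurred replicates 4 and 3 at −1.05 and −1.04, so scurred animals lay at both ends. Collagen and matrix genes were lowest in polled replicate 2 at −0.889 and highest in scurred replicate 4 at 0.506. Of 1005 genes with several tested probes, 741 had the same sign in all of them in polled against horned skin.

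Other splits of the same animals, tests chosen only after the results were seen, showed how often a grouping at random gives as much, though most of those for the horn types put animals of 1 chip in the same group. In polled against horned skin 2 of the 35 splits, the real one included, gave 1 probe or more (highest other 1), so chance is not excluded by that count. In scurred against horned and in polled against scurred skin the real count was 0, so 35 of 35 splits reached it in each, with a highest other of 1. Between the sexes 3 of 100 splits drawn from 462, the real one included, gave 3 probes or more, with a highest other of 5. That share is under 0.05, but in a draw of 100 it is too uncertain to exclude chance by the count alone. For the number of lists chance is not excluded in any comparison. As many as the real 18, 16, 8 and 8 lists were called in 5, 12 and 30 of the 35 splits and in 89 of the 100 between the sexes, with highest others of 21, 22, 23 and 23. Splits that part every pair of a chip, as the real one does, were 4, 4 and 8 for the horn types, too few for a share under 0.05. Their highest others were 16, 20 and 21 lists against the real 18, 16 and 8. In polled against scurred skin and between the sexes some splits called up to 23 lists against the real 8. A structure of the samples that the groups do not follow was not tested as the cause. A preset correlation that is too low can by itself raise such counts. With the means of the sexes removed, genes of a list correlated on average at 0.681 (cornified) down to 0.0104 (follicle stem cell). Every list lay above the preset 0.01, with a median of 0.342 for lists other than muscle. These values still hold any effect of horn type, but they argue that the preset value was too low for most lists. With an estimated correlation 0 lists passed in the real grouping.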
